A study of Mus musculus with 4 samples.

How the data were processed

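DNA methylation was measured by immunoprecipitation of methylated DNA followed by hybridisation to a tiling array (MeDIP-chip). In this assay the ratio of precipitated to total DNA at a probe rises with the methylation and the CpG density of the fragment, so it is a relative enrichment and not a percentage of methylated cytosines. Per the labels, total genomic DNA was extracted from fetal liver with a commercial kit, immunoprecipitated DNA was labelled with one dye and the total genomic DNA of the same pool with the other, and each pool was described as N = 6. The antibody, the fragmentation and any amplification are not given in the sources used here. The 4 arrays were grouped by their titles into the control pool and the food restricted pool, each with 1 array in each dye orientation. Slide 1 held both pools with immunoprecipitated DNA in Cy5, and slide 2 held both with immunoprecipitated DNA in Cy3. On both slides the control pool had the same array position and the food restricted pool the other, so position on the slide and pool cannot be told apart.

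Scanner output was made with Agilent Feature Extraction 10.5.1.1, per the submitters' processing notes and the file headers. Per the file headers, the processed intensity of each channel had local background subtracted, dim signals replaced by a surrogate value, and a linear dye factor applied within the array, with no normalization between arrays. The deposited scanner files also hold the median intensity of spot and background, background-subtracted intensities, and a log10 ratio of red over green, which the scanner software set to 0 at 1.04% to 1.57% of probes and which was not used for results. Flags for saturation, outliers and signal well above background were taken as deposited. Probe positions are on build mm9, per the file headers. Of 420288 spots, 4474 were control spots and 65 of the 415814 probes were left out for outlier flags, which left 415749. Probes had a median length of 59 bp.

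The deposited value table of the series holds log2 of red over green processed signal, not turned for the dyes and not centred, with column medians between -0.23 and 0.24. Its columns for the food restricted pool in the first orientation and the control pool in the second hold the values of each other's scanner file, equal within 0.001 at 100% of probes, and each correlates at r = -0.91 with the scanner file of its own sample. The scanner files were used as the main source because their red and green ratios run as the dyes in the titles require. The following measures pair the arrays in the same way. The share of immunoprecipitated probes well above background was 72.2% and 72.0% on the arrays assigned to the control pool and 79.9% and 80.6% on those assigned to the food restricted pool. The correlation of the channels over probes was 0.64 and 0.61 against 0.59 and 0.56. Array position was tied to the pool on both slides, so a position effect would give the same pairing. These measures therefore do not settle which arrays belong to which pool. In the alternative with the value table, each column was assigned to the sample whose scanner file it equals. A note on dye exchange stands in the labels of both food restricted arrays, although the titles place it between the slides.

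For each array, M was computed as log2 of processed immunoprecipitated over processed reference signal, turned by the dyes in the titles, and centred on the array median. No loess or quantile step was applied in the main setting, since most probes of such an array carry signal. With turned ratios, the arrays of 1 pool correlated over probes at r = 0.93 for the control pool and 0.94 for the food restricted pool. The control array of slide 1 also correlated at r = 0.93 with the food restricted array of slide 2. The control array of slide 2 correlated at r = 0.91 with the food restricted array of slide 1. This measure therefore does not settle which arrays belong to the control pool. Probes were joined into regions where neighbours lay at most 500 bp apart, up to a length of 2000 bp and with at least 3 probes. The resulting 56653 regions held 96.4% of probes. The value of a region was the median M of its probes, and D was the food restricted pool minus the control pool within a slide. A region was called when D was at least 0.5 in size with the same sign on both slides. Channel differences are differences of region medians of log2 signal, centred per channel and array, so they need not add up to D.

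No test was run. Each group was 1 pool, the 2 arrays of a pool were technical repeats, and a test would have measured the spread of the hybridisation alone. The count of regions past the size with opposite signs was set beside the calls as a gauge of noise that the slides do not share. It covers both orders of the slides, so a single direction was compared with this count divided by 2. Variation that both slides share, from the animals, the pooling, the precipitation and any amplification, is not in that gauge. The number of pools limits the precision, and signal over background limits it further in the immunoprecipitated channel. The steps from array values to calls were tested on simulated data for 56653 regions of the food restricted against control comparison. With a true log2 change of 1, 99 of 100 changed regions were recovered, and with 0.5, 31 of 100, none in the wrong direction. Among the unchanged regions 82 were called in either direction and 79 had opposite signs, far fewer than in the real arrays. The simulated noise had 1 size for all probes, so the recovery rates hold for that noise and not for the real arrays.

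Where fewer than 50% of the probes of a region were well above background in the immunoprecipitated channel on either array of a pool, the region is described as dim, or not well above background, in that pool. Its fold is then given as at least the ratio of the measured pool over the lowest signal well above background, or left out where that bound is under 1 or both pools are dim.

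The 17 gene lists fixed before the data were examined, the comparison of known methylated and unmethylated genes, and the comparison of promoters with other locations were not run. None of the probes carries a name other than its position, and the gene table in use is on another build, so no gene could be assigned. The ranking fixed for named genes, by the smaller D of both slides, was therefore applied to regions by position. That rule allowed up to 2 unnamed regions in each direction, and the wider set of 10 in each direction was chosen after the values were seen.

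The alternatives fixed before the data were examined were normexp background correction with an offset of 50, loess within arrays, quantile normalization between arrays, a linear fit of D on mean M, no centring, centring on the densest value, a filter on dim reference and saturated probes, means instead of medians over probes, the value table, leaving out X and Y, differences across slides, each slide alone, and other settings of region building and size. Normexp was run on median spot intensities, as mean intensities are not used here. Added after the data had been examined were the residual of D from its running median along mean M in 200 bins, the immunoprecipitated channel alone, a filter on dim immunoprecipitated probes, that filter together with the running median, and the division of regions into 10 classes by mean M. The dose of sex chromosomes was taken from reference signals relative to autosomal probes matched on brightness, with bootstrap intervals over probes. Normexp and loess were run with limma 3.58.1 in R 4.3.3, and all other steps in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.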

Results

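Genome-wide DNA methylation was profiled in the livers of C57BL/6J mouse fetuses whose mothers had received 50% of the chow eaten by control dams from gestation day 10 to 17, and in fetuses of dams fed freely. Livers were collected on gestation day 18. The study set out to look for genes behind the developmental origins of health and disease, the association of conditions before birth with illness in later life. Each group was represented by 1 pool of liver DNA, described as N = 6. Methylated DNA was immunoprecipitated from the pool and hybridised against the total genomic DNA of the same pool on a 2-colour tiling array. Each pool was hybridised on 2 arrays with the dyes exchanged, so that 4 arrays on 2 slides were available, and each slide carried both pools in 1 dye orientation. The 2 arrays of a pool are technical repeats of 1 sample. The difference between the pools therefore has no replicate check, no p-value was computed, and the values from both slides are given instead.

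The arrays measured 415749 usable probes, which were summarised as 56653 regions with a median of 7 probes and a median length of 1326 bp. Enrichment is given as M, the log2 ratio of immunoprecipitated to reference signal after centring each array on its median, and D is M of the food restricted pool minus M of the control pool on the same slide. The immunoprecipitated signal was dimmer in the control pool, with a median background-subtracted signal of 39.1 on slide 1 and 29.5 on slide 2, than in the food restricted pool, with 63.2 and 43.8. Well above background were 72.2% and 72.0% of the immunoprecipitated probes of the control pool and 79.9% and 80.6% of those of the food restricted pool. In the reference channel the share lay between 93.5% and 97.6% on all 4 arrays. M over regions correlated between the arrays of 1 pool at r = 0.965 for the control pool and 0.972 for the food restricted pool. Between an array of each pool on different slides, which like the repeats differ in slide and dye, it was 0.964 and 0.953, and between the pools on 1 slide, where slide and dye orientation are shared, 0.969 on both slides. These correlations run across regions, which are not independent replicates.

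Enriched regions were distributed over the chromosomes in the same manner in both pools. On the autosomes 30.1% of regions had M above 1 in the control pool and 28.2% in the food restricted pool. Chromosome 15 had the highest autosomal share, 37.4% in the control pool and 34.6% in the food restricted pool, and chromosome 13 had the lowest, 25.7% and 23.7%. The X chromosome stood below all autosomes, with 17.8% and 16.4% of its 2072 regions. The standard deviation of M over regions was 1.51 in the control pool and 1.45 in the food restricted pool on slide 1, and 1.49 and 1.46 on slide 2.

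**Figure D1:**
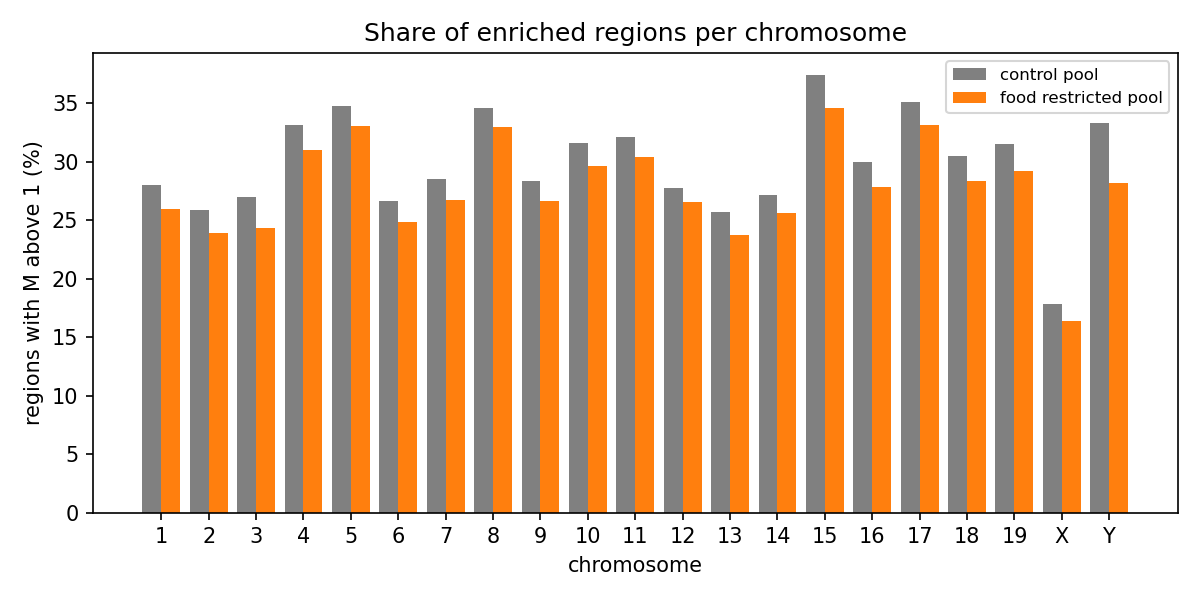
Percentage of regions with M above 1 on each chromosome in the control pool (grey bars) and the food restricted pool (orange bars), each from the mean of its 2 arrays. Chromosome 15 has the highest shares among autosomes (37.4% and 34.6%) and X the lowest of all chromosomes (17.8% and 16.4%); Y rests on 39 regions.

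The main comparison asked where the livers of fetuses from food restricted dams differed in methylation from those of controls. In total, 2580 regions were higher in the food restricted pool and 364 were lower, taking a D of at least 0.5 in size, or 1.41-fold, with the same sign on both slides. A further 406 regions passed this size on both slides with opposite signs, which is a gauge of the noise that is independent between the slides. The median size of the mean D corresponded to 1.67-fold over all 2580 higher regions and 1.69-fold over all 364 lower ones. Regions not well above background are included in both medians, and 1916 higher and 170 lower regions were dim in neither pool. Across all regions D on slide 1 and D on slide 2 correlated at r = 0.34. Opposite signs cover both orders of the slides and each direction covers 1, so such noise without any change would put 203 regions in each direction. The higher regions were 12.7 times and the lower regions 1.79 times this number. The number takes D to have no shift that the slides share, and a shared shift upwards raises the higher count without being noise of 1 slide. With the running median of D along mean M taken off, the higher regions were 2.64 times and the lower regions 2.41 times the number for that setting. The gauge leaves out what both slides share, and without dim reference and saturated probes the lower regions fell below it, with 128 against 166.

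The excess of higher regions depended on how the arrays were scaled. Of all called regions 87.6% were higher in the main setting. Centring each array on its densest value instead of the median gave 1063 higher and 738 lower regions, or 59.0% higher, and moved the median D of all regions to -0.22 on slide 1 and 0.10 on slide 2, from 0.04 and 0.09. Without centring, the median D was 0.14 and 0.15 and the counts were 4071 and 227. Quantile normalization between the arrays gave 668 and 581 regions, or 53.5% higher, with 446 of opposite signs. When D was instead taken across the slides, with no block for the slide, the correlation fell to 0.0073 and 1658 regions had opposite signs. In that setting a slide or dye effect enters D with opposite signs by construction.

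Higher regions were found at both ends of the range of enrichment. When regions were divided into 10 equal classes by their mean M over the 4 arrays, 1802 of the 2580 higher regions lay in the 5 classes with the lowest M and 702 in the class with the highest. Only 76 lay in the 4 classes between. In the highest class, 12.4% of the 5666 regions were called higher, none was called lower, 2 had opposite signs, and D correlated between the slides at r = 0.68. These calls followed the level: with the running median of D along mean M taken off, 5 regions of this class were higher and 2 lower. At probes with mean M from 3 to 4 the median D was 0.32 and 0.48 on the slides, and above 4 it was 0.84 and 1.02. In the lowest class, 11.4% were called higher and 0.141% lower, with r = 0.16. Lower regions lay mainly in the middle of the range, with 204 in classes 6 to 9 and 160 in classes 1 to 5. This division was made after the data had been examined.

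**Figure D2:**
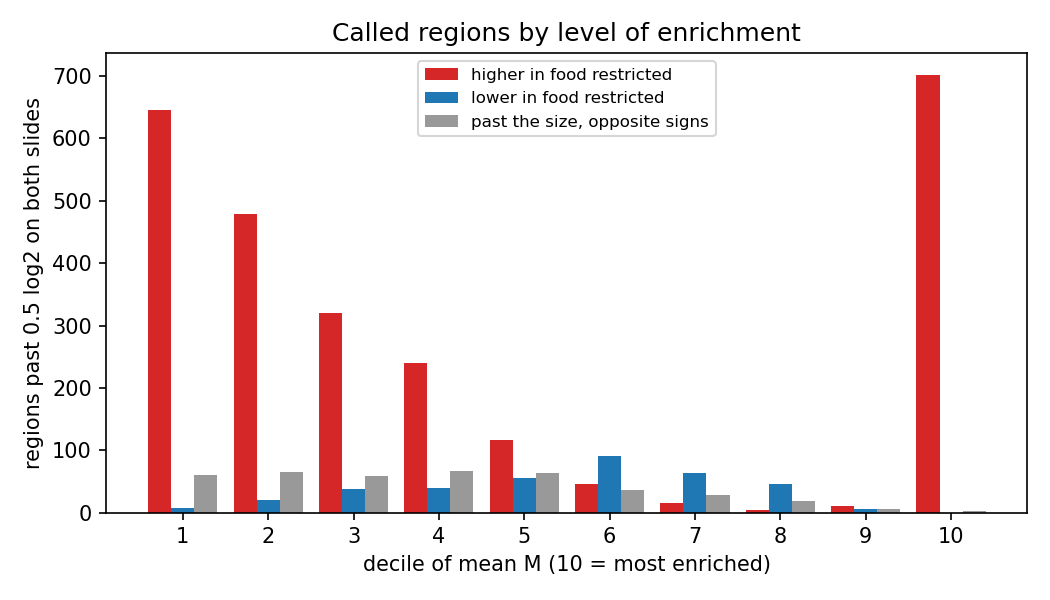
Number of regions past 0.5 log2 on both slides in each of 10 equal classes of mean M, by whether they were higher (red) or lower (blue) in the food restricted pool or had opposite signs on the slides (grey). Higher regions number 646 in class 1 and 702 in class 10, against 4 in class 8.

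The channels behind these differences were not the same at the ends of the range. In the 702 higher regions of the highest class, the median D was 0.68 on slide 1 and 0.82 on slide 2, while the immunoprecipitated signal, centred on its array median, was lower in the food restricted pool by a difference of -0.38 and -0.31. The reference signal of these regions differed by -0.75 and -0.80. In the 1802 higher regions of classes 1 to 5, D was 0.71 on both slides, the immunoprecipitated signal was higher in the food restricted pool by 0.57 and 0.51, and the reference signal by 0.18 and 0.17. At the 7490 probes with mean M above 4, the centred reference signal was 0.61 and 0.69 in the control pool but -0.40 on both slides in the food restricted pool. Among the 364 lower regions, the median D was -0.73 and -0.74, with an immunoprecipitated difference of -0.36 and -0.33, against -0.14 and -0.13 over all regions, and a reference difference of 0.18 and 0.21. In the immunoprecipitated channel alone, 634 of the 2580 higher regions and 45 of the 364 lower regions were called in the same direction.

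**Figure D3:**
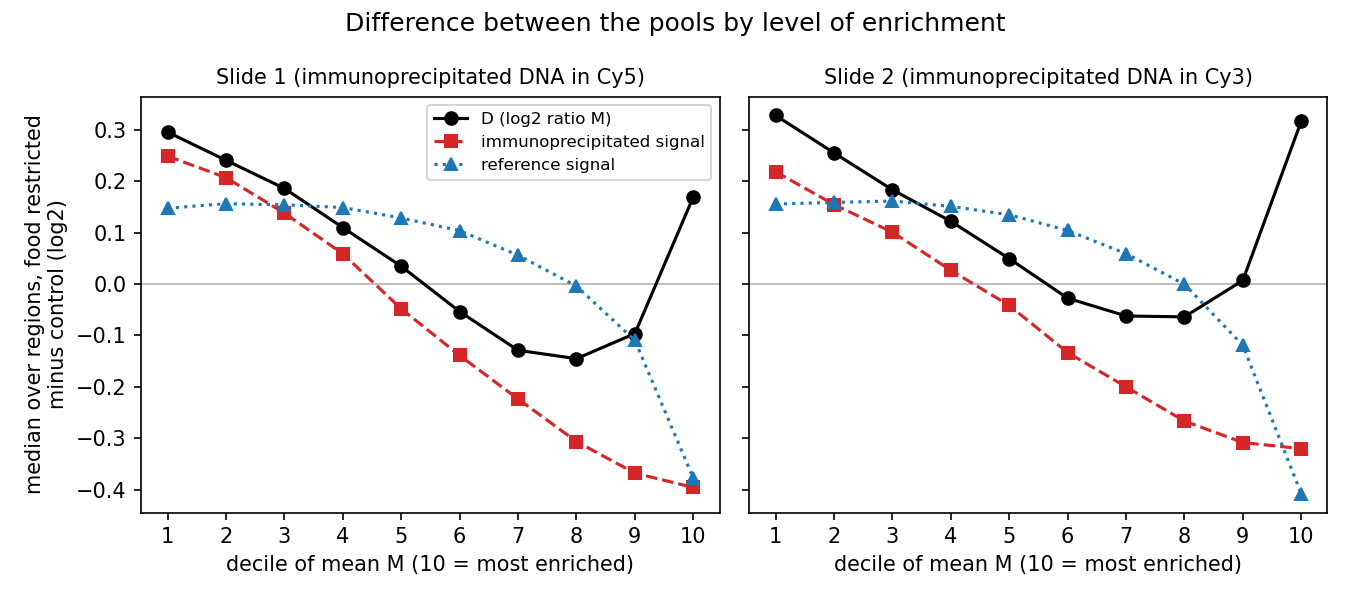
Median difference between the pools (food restricted minus control, log2) in each of 10 equal classes of mean M on slide 1 (left) and slide 2 (right), for D (black circles), the immunoprecipitated signal (red squares) and the reference signal (blue triangles). D is positive in class 1 (0.30 and 0.33) and class 10 (0.17 and 0.32), and the reference signal falls to -0.38 and -0.41 in class 10 on both slides.

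Part of the calls rested on dim probes. In 662 of the 2580 higher regions (25.7%) the immunoprecipitated signal of the control pool was not well above background, and in 190 of them neither pool was. Among the 364 lower regions the control pool was dim in 186 (51.1%) and both pools were dim in 165. After probes with a dim reference signal or saturation were left out, 2869 higher and 128 lower regions were called, and of the original calls that could still be measured, 2317 of 2523 higher regions (91.8%) and 72 of 241 lower regions (29.9%) kept their call. After dim immunoprecipitated probes were left out instead, 1089 of 1707 higher regions (63.8%) and 20 of 145 lower regions (13.8%) did.

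Single regions are given by position on the mm9 build, because the files name probes by position only and an annotation of that build was not used here. Among the 10 higher regions ranked first by the smaller D of the slides, 9 lay in classes 1 to 5 and 1 in the highest class. The first, on chromosome 6 from 40949456 to 40950103 (3 probes), had a mean D of 2.03, with 2.06 and 2.00 on the slides. It was not well above background in the control pool, the food restricted pool was at least 1.42-fold higher, and with normexp correction its mean D was 0.32. The second, on chromosome 9 from 71958613 to 71959630 (5 probes), was measured in both pools and was 3.45-fold higher, with D of 1.74 and 1.84, but its mean D was 0.60 once dim immunoprecipitated probes were left out, 0.42 with the running median also taken off, and 0.068 with loess normalization. A region of 7 probes on chromosome 6 from 87862888 to 87863997 was 3.31-fold higher, with D of 1.38 and 2.07, but its mean D was 0.085 with loess, 0.43 with means over probes, 0.45 with normexp and 0.46 in the immunoprecipitated channel alone. On chromosome 2, the region from 24008530 to 24009057 was 2.90-fold higher on 3 probes. Its mean D was 0.19 with loess, 0.51 with means over probes and 0.49 in the immunoprecipitated channel alone. That channel differed by 1.13 on slide 1 but by -0.16 on slide 2. The region was not measured once dim reference or dim immunoprecipitated probes were left out. On chromosome 9, the region from 121551478 to 121552534 was 2.64-fold higher on 4 probes, with a mean D of 0.18 with normexp and 0.61 with loess. In the control pool 2 of these probes were well above background in the immunoprecipitated channel. This region was not measured once dim immunoprecipitated probes were left out.

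The region on chromosome 2 from 30110608 to 30111715 was also 2.64-fold higher by the ratio, from an M of 3.78 in the control pool to 5.18 in the food restricted pool. Its immunoprecipitated signal differed by -0.26 and -0.17 on the slides and its reference signal by -1.20 and -1.17, so in the immunoprecipitated channel alone its mean D was -0.21, and it was 0.40 with quantile normalization. Of the other 4 regions, those on chromosome 7 (27335718 to 27336139), chromosome 16 (17402598 to 17403330) and chromosome 3 (14530800 to 14531301) were dim in the control pool, with a fold of at least 1.09 for the last and no fold for the others. The region on chromosome 2 from 111978912 to 111980269 was dim in both pools, and with normexp background correction its mean D was -0.024.

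Of the 10 lower regions ranked first, 7 were dim in both pools in the immunoprecipitated channel and have no fold. The first of all, on chromosome 7 from 92062550 to 92063654 (5 probes), had D of -1.62 and -1.50, with a reference signal that was higher in the food restricted pool by 1.49 and 1.19. Another dim region on chromosome 7, from 93023602 to 93024545, had D of -1.32 and -1.15. The others lay on chromosome 4 (108395530 to 108397102), chromosome 5 (83785802 to 83786670), chromosome 6 (56906146 to 56906427), chromosome 9 (38396887 to 38397921) and chromosome 14 (51271740 to 51272779). Another 3 lower regions were measured in both pools. The region on chromosome 2 from 164017743 to 164018228 was 2.69-fold lower, with D of -1.37 and -1.49 on 3 probes, but a mean D of -0.25 with loess. Its immunoprecipitated signal differed by -0.63 on slide 1 but by -0.043 on slide 2. This region was not measured once dim reference or dim immunoprecipitated probes were left out. The regions on chromosome 11 from 3862021 to 3863532, 2.71-fold lower, and on chromosome 1 from 174137477 to 174138804, 2.24-fold lower, had a mean D of 0.34 and 0.32 once dim immunoprecipitated probes were left out, so their direction rested on dim probes. With normexp correction the mean D of all 10 lower regions lay between -0.11 and 0.014.

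Among the autosomes, the share of higher regions ranged from 3.68% on chromosome 1 to 5.44% on chromosome 13, and the share of lower regions from 0.133% on chromosome 18 to 1.02% on chromosome 19. On the X chromosome 113 of 2072 regions (5.45%) were higher and 30 (1.45%) were lower, against 4.52% and 0.605% of autosomal regions. Opposite signs were also more frequent on X, with 41 regions (1.98%) against 0.666% of autosomal regions, so that against the noise in 1 direction the higher regions of X were 5.51 times and the lower regions 1.46 times as many, below the 13.6 and 1.82 times of the autosomes. The median D of X was 0.08 and 0.10 on the slides, or 0.03 above the autosomes on average. This distance was 0.049 on slide 1 and 0.0065 on slide 2. It turned to -0.040 with normexp correction and to 0.13 in the immunoprecipitated channel alone. On Y, 4 of 39 regions were lower and none was higher, and the median D was -0.21 and -0.18. With dim immunoprecipitated probes left out, Y lay 0.053 above the autosomes.

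Because the sex of the pooled fetuses is not given in the sources used here, the dose of the sex chromosomes was compared in the reference DNA. Against autosomal probes of like brightness, the reference signal of X differed between the pools (food restricted minus control) by 0.06 on slide 1 and 0.02 on slide 2, with bootstrap intervals over probes from 0.051 to 0.062 and from 0.019 to 0.028. The 272 probes of Y differed by -0.002 and -0.03, with intervals from -0.07 to 0.05 and from -0.06 to 0.03. With normexp correction the matched differences on slides 1 and 2 were 0.019 and 0.0054 for X and 0.0036 and -0.0039 for Y. Without matching on brightness, the processed reference signal differed by 0.080 and 0.069 for X and by 0.065 and 0.11 for Y. The bootstrap intervals cover the spread over probes of 1 pool per group. The sources do not state whether N = 6 counts fetuses or litters, so no sex makeup of the pools was derived.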

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

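The running median, the immunoprecipitated channel alone and the filter on dim immunoprecipitated probes, alone and with the running median, were chosen after the results had been seen. Higher regions outnumbered lower ones in each of the 23 alternatives that were run, but which regions were called changed: of 2580 higher regions, 1 was called in all 10 of the alternatives fixed beforehand that keep the regions and use both slides, and of 364 lower regions 0 were, against 182 and 2 when normexp and loess were left aside. Unless stated, the cause of a change was not tested.

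Normexp correction gave 1552 higher, 1 lower and 1 opposite region with r = 0.59 between the slides; its offset shrinks dim signals by construction. Loess gave 4826 higher and 237 lower with r = 0.54, quantile normalization 668, 581 and 446 opposite with r = 0.19, and the linear fit on mean M 1642, 702 and 453. No centring gave 4071 and 227, and the densest value 1063, 738 and 694 opposite. Without dim reference and saturated probes 128 were lower. With means over probes 107 were lower and 88 opposite, with r = 0.44. The running median gave 620, 566 and 469 opposite with r = 0.18. The immunoprecipitated channel alone gave 977 lower and 582 opposite with r = 0.43. Without dim immunoprecipitated probes there were 1709 higher, 67 lower and 90 opposite with r = 0.45, and with the running median as well 403, 110 and 103 with r = 0.25.

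By construction, a size of 0.25 gave more calls (8621 higher, 2290 lower, 3014 opposite) and a size of 1 fewer (109, 24 and 12). Gaps of at most 250 bp gave 635 opposite regions. The mean D of both slides past the size gave 5417 higher and 1038 lower. A single slide, without replicate 1 or without replicate 2, gave 6998 to 7799 higher and 2124 to 2542 lower, and allows neither an opposite count nor a correlation. With no replicate block, D across the slides gave r = 0.0073 and 1658 opposite regions, against 0.34 and 406 with the slide as a block. By construction, a slide or dye effect then enters D with opposite signs, which lowers r and adds opposite regions. Lower regions exceeded the opposite count in 9 of the 20 alternatives that give one, and that count divided by 2 in 18, but not without dim reference probes or across the slides. At least 5 probes, gaps of at most 1000 bp and leaving out X and Y kept all counts within 1.5 times. The value table did so by construction, since its columns hold the values of the scanner files.

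The distance of the median D of X from the autosomes, 0.03, became -0.040 with normexp, -0.058 with loess, -0.0034 with means, 0.13 in the immunoprecipitated channel and -0.011 without dim immunoprecipitated probes. That of Y, -0.26, became -0.080, -0.055, -0.23, -0.061 and 0.053, with -0.11 without dim reference probes and -0.092 without dim immunoprecipitated probes under the running median. The reference signal of X relative to matched autosomal probes was 0.040, and 0.012 with normexp.

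Direction changed for 6 of the 20 named regions. The mean D of the region at 3862021 on chromosome 11, -1.44, became 0.050 without dim reference probes, 0.19 in the immunoprecipitated channel, 0.34 without dim immunoprecipitated probes and 0.17 with the running median added. For 174137477 on chromosome 1 it was 0.32 and 0.39 in the last of these. For 108395530 on chromosome 4 it was 0.39 without dim reference probes and 0.75 in the immunoprecipitated channel. For 83785802 on chromosome 5 it was 0.014 with normexp, 0.23 with loess and 0.30 in the immunoprecipitated channel. For 30110608 on chromosome 2 it was -0.21 in that channel, and for 111978912 on chromosome 2 -0.024 with normexp. No change of sign was found in the other 14 where they were measured, but 5 of the 20 were measured without dim immunoprecipitated probes and 12 without dim reference probes. Promoter alternatives and all alternatives for gene lists were not run, since no probe had a gene. Signal over background limits the regions of low M most: in the lowest class 44.9% of immunoprecipitated probes of the control pool were well above background, against 98.4% in the highest.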

Other observations

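Of the tests given here, the bleed-through test and both counts of single regions were set out before their results were seen, and the others afterwards.

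A set of 52 higher regions combined several properties. They were called in the ratio, in the immunoprecipitated channel alone, without dim immunoprecipitated probes, and with the running median of D along mean M taken off with and without those probes. Only 3 lower regions and 1 region with opposite signs met the same rules. Of all 2580 higher regions, 1 was called in all 10 alternatives fixed beforehand and 33 when normexp was left aside. At most 1 of the 52 was therefore called in all of those alternatives. The 52 lay on 16 chromosomes, 47 of them in the lower 5 classes of M, with a median fold of 1.97 among the 51 that have one, and their median M was -1.25 in the control pool and -0.30 in the food restricted pool. Ranked first by the smaller D was a region of 5 probes on chromosome 13 from 54891007 to 54891700, 2.45-fold higher, with D of 1.28 and 1.30. A region of 9 probes on chromosome 1 from 140737567 to 140739091 was 2.28-fold higher, with D of 1.23 and 1.15. The region from 117283520 to 117283919 on chromosome 12 was 1.86-fold lower, with D of -0.83 and -0.96. These positions were chosen after their values were seen.

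The first pattern is the higher M of the food restricted pool in the most enriched class of regions. A larger precipitated amount of these regions in that pool would raise the immunoprecipitated difference between the pools above that of classes 6 to 9, but it changed by -0.12 and -0.080 on the slides. Dye bleed-through would need a weaker immunoprecipitated signal in the food restricted pool relative to the reference brightness, and that signal was higher by 0.30 and 0.23. A different makeup of the reference DNA in the pools remains a candidate explanation. The reference difference fell by 0.39 and 0.43 from classes 6 to 9 to the highest class while D rose by 0.28 and 0.35. As D is built from both channels, this fall places the change in the reference channel without showing its cause. Whether such a difference in total DNA arose in handling or in the fetuses was not tested, and array position stays tied to the pool.

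The second pattern is the higher M of the food restricted pool in the lower 5 classes. Probes not well above background are not its whole source, since in the 16735 of 28327 regions that could be measured without them 67.1% and 73.1% of the median D were left; the other regions were not in this test. Less selective precipitation in the food restricted pool and a broad gain of methylation at weakly enriched regions cannot be told apart, since either gives a shift along the level that the running median takes off; of single regions 506 higher and 434 lower were then left, 2.73 and 2.34 times the number that noise apart on the slides would put in each direction, and without dim immunoprecipitated probes 338 and 88, or 7.60 and 1.98 times. A gain of methylation at single regions may lie beneath. The 52 regions above outnumber both gauges, but some of their rules keep the shift along the level, which favours higher calls in these classes. With the trend taken off in every setting, 60 regions were higher, 4 lower and 1 opposite. With 1 pool per group, a precipitation that differed by chance between the pools would give the same counts, so effects of food restriction stay untested.

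The last pattern is the set of 364 lower regions. A lower precipitated amount stays open: 12.4% were also lower past the size in the immunoprecipitated channel alone. The median immunoprecipitated difference of the set was -0.36 and -0.33 on the slides, against -0.14 and -0.13 over all regions. D is built from this channel, so choosing regions by a low D lowers this difference by selection alone. The comparison with all regions therefore cannot decide the question. Signal near background in either channel is a candidate source. Of the regions still measured, 29.9% kept their call once dim reference probes were left out and 13.8% once dim immunoprecipitated probes were. A region that lost its call can still have a D below 0.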
